A study of Mus musculus with 26 samples.

How the data were processed

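Leukocytes sorted from mouse femoral bone marrow were profiled on Illumina MouseRef-8 v2.0 beadchips from cDNA made with NuGEN amplification and biotin labelling kits. Per the labels, the 26 arrays belong to 3 conditions (control, restraint, restraint plus propranolol) in 2 experiments, with 5, 5 and 3 arrays in each experiment. GenomeStudio is the only tool that the submitters' processing notes name, and no version is given. The deposited raw matrix holds, per probe and array, the mean bead signal as an intensity that is neither background-subtracted (its lowest value is 96.0) nor scaled between arrays, for 25697 probes. Per the file headers, the same matrix gives a detection p-value for each probe and array. The normalized matrix that the authors deposited holds intensity on a linear scale for 18138 gene symbols, 18116 of them also in the raw matrix. Its method is not stated. The median of its percent differences from a quantile normalization of the raw arrays averaged per symbol was 0.753%, and the largest was 5.41%. A second deposited copy of these normalized values differed by at most 0 at the 18110 shared symbols. The raw matrix holds 6 further arrays that the labels put in no group, and they were not used for any value given here. The genome build of the annotation is not given, so genes are named by symbol and probe.

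Raw intensities were corrected for background with limma's neqc, which infers the negative controls from the detection p-values, adds an offset of 16, quantile normalizes and takes log2. Probes detected at p under 0.05 on at least 3 arrays were kept, 15061 in all. Probes were named by Entrez identifier (23788), accession (1148), current symbol (99) or synonym (98), and 564 kept the name in the file. Of the 10792 genes kept, 2887 had several kept probes, and the probe with the highest mean stood for the gene. The probes of a gene did not always change alike, and an alternative averaged them. Linear models with condition and experiment were fitted to all probes with limma, with moderated variances and Benjamini-Hochberg adjustment over all 15061 probes, and a gene was called when its adjusted p was under 0.05. A model with all 6 groups gave the changes within each experiment and the difference between experiments, the interaction. The number of arrays that show a direction was counted against the mean of the other condition in the same experiment. For a gene detected on no array of a group, the fold change is given as a lower bound against the detection floor. R 4.3.3, limma 3.58.1, data.table version 1.17.8 and matplotlib 3.10.9 were used.

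Before the data were examined, the conditions compared, the gene lists, the rule for named genes and all alternatives but those described as added were fixed. The composites and lists were written from general knowledge and are not the gene sets of the study's own composites. The DNA repair composite joins 6 lists: base excision, mismatch and nucleotide excision repair, homologous recombination and Fanconi anemia, non-homologous end joining, and damage signalling and other repair. The SASP composite joins 2 lists: soluble factors, and proteases, receptors and matrix. The other pathway lists are cell cycle inhibitors and p53 targets, proliferation, immediate early and cAMP response, glucocorticoid response, proinflammatory CTRA genes, type I interferon response, MHC class II presentation, heat shock, ribosomal proteins and oxidative phosphorylation. The 15 cell type lists hold markers of neutrophil primary granules, secondary granules and mature neutrophils, monocytes, macrophages, erythroid cells, megakaryocytes and platelets, B, T and NK cells, dendritic cells, eosinophils, basophils and mast cells, stem and progenitor cells, stromal, endothelial and bone cells, and osteoclasts. Lists share members, so their tests are not independent. A list's value on an array is the mean log2 intensity of its measured genes. Differences are means of the within-experiment differences, tested 2-sided with an exact permutation of the conditions within experiments (63504 relabellings of restraint and control, 3136 for either comparison with propranolol). The tests were adjusted over 6 composite tests and 99 list tests. Camera with a preset correlation of 0.01 and with an estimated correlation, and fry, were run beside it. Camera sets a list against the other genes. The exact test asks whether a list's mean per array differs between conditions, and that mean keeps the correlation between members. Of the 16 list calls, 0 held with the estimated correlation. For 13 pairs of list and comparison, 0 of them past the test, the mean, the median and camera differed in sign. The difference between experiments was also tested for all lists and composites (105 tests).

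Named genes were chosen by rule: for each comparison the 10 largest rises and 10 largest falls among called genes with the same sign in both experiments, or, where fewer passed, up to 5 per direction of smallest p, given as not called, then up to 4 members of each list with the smallest p, and 16 genes named whatever their value. Some genes that the rule names are not reported here. The steps were tested on simulated data of the same layout. For restraint against control, 32.2%, 81.9% and 96.8% of probes changed 1.5-fold, 2-fold and 3-fold were called, and 0.0511% of unchanged probes. With fewer arrays, these were 24.1%, 63.6%, 92.1% and 0.0148% for restraint plus propranolol against restraint, and 24.4%, 64.1%, 91.2% and 0.00135% against control. In each comparison the exact test had an unadjusted p under 0.05 for 40 of 40 lists of 20 random genes shifted by 0.25 and for 1 of 40 unshifted lists. Random genes do not vary together as members of a list can, so these shares do not give the power for the lists tested. Replicate numbers were not taken as pairs: among 22 pairs of arrays with the same number the correlation of residuals ran from -0.258 to 0.332, and 6 of 26 arrays correlated best with an array of their own number. The analysis of transcription factor binding motifs that the series design mentions was not carried out here.

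The alternatives were the deposited normalized matrix, no background correction, normexp with an offset of 50, median scaling, no filter and a stricter filter on dim probes, the mean of a gene's probes, slide as a fixed term or random block, a replicate block, array weights, a variance model with trend and robust estimation, a fold change of at least 1.5, only the conditions compared, z-scores, both camera settings, each experiment alone, and each of the 26 arrays left out in turn. Added after seeing the data were a fit without the 3 arrays with an array weight under 0.3 (experiment 1 control replicate 5, experiment 2 control replicate 4 and experiment 2 restraint plus propranolol replicate 3) and comparisons within a slide, on slide 3 also without control replicate 4.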

Results

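Gene expression was measured in leukocytes sorted from the femoral bone marrow of male SCID mice aged 6 to 8 weeks. The mice had been engrafted with human acute lymphoblastic leukemia, and the sort left leukemia cells out. Mice were randomized to control conditions, to restraint stress, or to restraint stress with propranolol, a blocker of beta-adrenergic receptors. Each condition was run in 2 experiments. The 26 arrays comprise 5 control, 5 restraint and 3 restraint plus propranolol arrays in experiment 1 and the same numbers in experiment 2, which gives 10, 10 and 6 arrays per condition. The labels do not say whether each array comes from a separate mouse. Per array, 39.5% to 51.2% of the 25697 probes were detected above background, and the median raw signal lay between 124 and 156. The share of detected probes was 46.8% on restraint arrays and 48.2% on control arrays, a difference of -1.49 points (exact permutation p = 0.163). After the detection filter, 15061 probes of 10792 genes were tested. The number of arrays limits the precision of every value.

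The first comparison, restraint against control, addresses whether restraint stress alters transcripts tied to biological aging, among them DNA repair genes and the senescence-associated secretory phenotype (SASP), the set of factors that senescent cells release. In marrow from restrained mice, proinflammatory, glucocorticoid response and p53 target transcripts were higher, and transcripts of red cell precursors, B cell precursors and DNA repair were lower. None of these group calls held with a correlation between genes estimated by camera (adjusted p = 0.0676, 0.0864 and 0.0676, and 0.184, 0.128 and 0.0843 with an estimated correlation). Camera sets a list against the other genes, a different question from that of the exact test of a list's mean. Cd83 (probe ILMN_2865016, chromosome 13), a surface protein of activated antigen-presenting cells, rose 2.99-fold (log2 change 1.58 ± 0.17 SE, 10 restraint against 10 control arrays, limma adjusted p = 2.0e-05). It was higher on 10 of 10 restraint arrays than the control mean of its experiment. Eraf, which encodes the alpha-hemoglobin stabilizing protein, was lower (limma adjusted p = 0.0330). It was detected on 10 control arrays and on 5 restraint arrays, so that its log2 change of -3.30 ± 0.82 SE is not an exact size. In total 241 genes passed limma's adjusted p threshold of 0.05, of which 112 rose and 129 fell, and 191 of them changed by at least 1.5-fold (85 up, 106 down). All 241 had the same sign in both experiments.

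The 10 genes with the largest rises were Rhov, Dusp4, Il1a, Cd83, Hcar2, Cd274, Grasp, Nlrp3, Pim1 and Hey1, with log2 changes from 1.68 for Rhov to 1.29 for Hey1. Il1a encodes interleukin 1 alpha, Cd274 the T cell inhibitory ligand PD-L1, Nlrp3 an inflammasome sensor, and Dusp4 a phosphatase that switches off MAP kinases. The other probes of some of these genes changed less: the lowest was 0.16 for Dusp4 and 0.15 for Pim1, and among the falls below Trim10 had a probe at -0.70. Among the 10 largest falls were those of Eraf, Slc38a5, Rhd, Alas2, Btnl10, Slc6a9, Abcb4, Trim10 and Tlcd4. Their sizes and order are not exact, as most of these genes were near background after restraint: Slc38a5, Rhd and Slc6a9 were detected on 4 of 10 restraint arrays, and Btnl10 and Trim10 on 1. Several of these belong to red cell precursors: Alas2 starts heme synthesis in erythroid cells (log2 change -2.63 ± 0.67 SE), and Rhd encodes a Rh blood group protein (-2.95 ± 0.77 SE). Tlcd4 was detected on 7 control arrays and on 0 restraint arrays, so that it was at least 3.16-fold lower after restraint.

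DNA repair transcripts were lower as a group after restraint. The mean log2 intensity of the 126 measured genes of the DNA repair composite was 6.73 ± 0.10 (SD, n = 10) on restraint arrays and 6.87 ± 0.08 (SD, n = 10) on control arrays. The difference was -0.14 ± 0.04 SE (2-sided exact permutation within experiments, p = 0.00227, adjusted p = 0.0068 over 6 composite tests), -0.19 in experiment 1 and -0.10 in experiment 2, and 9 of 10 restraint arrays lay below their control mean. Of the 126 genes, 93 had a negative and 33 a positive log2 change. By themselves 1 gene rose, 1 fell and 124 did not pass, and adjusted over the list alone these counts were also 1 and 1. With an estimated correlation between genes, camera gave the composite an adjusted p = 0.0843. Of the 6 repair lists, homologous recombination and Fanconi anemia fell by 0.28 (± 0.07 SE, 27 genes, exact adjusted p = 0.00156, lower on 10 of 10 arrays) and damage signalling by 0.14 (± 0.04 SE, 42 genes, exact adjusted p = 0.0194, lower on 9 of 10 arrays). Their adjusted p were 0.184 for both with an estimated correlation. Blm, a helicase that resolves recombination intermediates, was the recombination gene that passed by itself (log2 change -1.04 ± 0.26 SE, limma adjusted p = 0.0367). The 4 kept probes of Blm ran from -1.08 to 0.09, so that its fall is not shown by each of them. In this list 4 members fell adjusted over the list alone. The damage signalling member that passed by itself, Per1, rose (0.81 ± 0.21 SE, limma adjusted p = 0.0411), against the direction of its list. Per1 is a circadian clock gene that glucocorticoids induce, and it also stands in the glucocorticoid and immediate early lists. The other repair lists did not pass: base excision repair (-0.09, exact adjusted p = 0.186), mismatch repair (-0.16, 0.242), nucleotide excision repair (-0.07, 0.411) and non-homologous end joining (-0.00, 0.981). On the same restraint arrays the erythroid and B lineage marker means were lower by log2 differences of -1.58 and -0.88.

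Proinflammatory genes rose as a group. The 16 measured proinflammatory genes of the conserved transcriptional response to adversity (CTRA), a stress-associated expression profile, rose by 0.44 ± 0.08 SE on the log2 scale, from 7.90 ± 0.22 (SD, n = 10) to 8.34 ± 0.16 (SD, n = 10). In this text CTRA stands for this list alone and not for the whole profile. The exact permutation p was 3.1e-05, the smallest the 63504 relabellings can give (adjusted p = 0.00156; adjusted p = 0.0676 with an estimated correlation), and 10 of 10 restraint arrays lay above their control mean. Of its members 6 rose, 1 fell and 9 did not pass, and adjusted over the list alone 8 rose and 1 fell. Tnf (log2 change 1.08 ± 0.19 SE), Rel (0.98 ± 0.15 SE) and Nfkb2 (0.76 ± 0.16 SE), the latter being subunits of NF-kappaB, rose, as did Fosb (0.78 ± 0.16 SE), while Fos fell by 0.76 (± 0.18 SE). The SASP composite (45 genes) was 7.19 ± 0.16 (SD, n = 10) after restraint and 6.98 ± 0.22 (SD, n = 10) in controls. Its difference of 0.21 ± 0.11 SE did not pass (exact permutation p = 0.0331, adjusted p = 0.0569), although 10 of 10 restraint arrays lay above their control mean, and with an estimated correlation its adjusted p was 0.0843. Within it Icam1, an adhesion molecule (0.89 ± 0.14 SE, limma adjusted p = 0.00112), and Il1a rose and 43 genes did not pass. Neither of its parts passed: 0.20 for soluble factors (exact adjusted p = 0.270) and 0.23 for proteases, receptors and matrix (exact adjusted p = 0.0525). The means of mature neutrophil (0.07, exact adjusted p = 0.617) and monocyte markers (0.16, exact adjusted p = 0.411) did not pass on these arrays.

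Stress-response lists rose as well. Cell cycle inhibitors and p53 targets rose by 0.25 ± 0.06 SE (20 genes, exact adjusted p = 0.0207, higher on 9 of 10 arrays; adjusted p = 0.0676 with an estimated correlation), with Gadd45b (1.09), Bbc3 (0.47) and Cdkn1a (0.69), the gene of the cell cycle inhibitor p21, past the test and 17 genes not passing. Glucocorticoid response genes rose by 0.25 ± 0.05 SE (17 genes, exact adjusted p = 0.00935, higher on 10 of 10 arrays; adjusted p = 0.0864 with an estimated correlation), with Per1, Nfkbia (0.84), the gene of an NF-kappaB inhibitor, and Ddit4 (0.71) past the test and 14 genes not passing. The known target Tsc22d3 was among the 14 (-0.11 on the chosen probe and 0.39 on its other). Immediate early and cAMP response genes rose by 0.28 ± 0.09 SE (25 genes, exact adjusted p = 0.0493, higher on 9 of 10 arrays), 0.46 in experiment 1 and 0.10 in experiment 2. This call is at the threshold: it held in 5 of the 26 fits with 1 array left out. Some of the losses came from restraint plus propranolol arrays, which do not enter this difference and move only the adjustment. The list call did not hold when camera estimated the correlation between genes (adjusted p = 0.379). Here 5 members rose, among them the cAMP phosphodiesterase gene Pde4b (1.08) and the nuclear receptor gene Nr4a2 (0.74), 1 fell (Fos) and 19 did not pass. Proliferation genes (-0.25, exact adjusted p = 0.0598) and MHC class II genes (0.42, exact adjusted p = 0.0947) did not pass as lists, although Ccna2 fell (-0.63 ± 0.17 SE, limma adjusted p = 0.0472) and H2-Ab1 rose (0.64 ± 0.17 SE, limma adjusted p = 0.0486).

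Markers of 2 blood lineages fell beside these changes. The 14 erythroid markers fell by 1.58 ± 0.43 SE on the log2 scale, from 7.79 ± 1.14 (SD, n = 10) to 6.22 ± 0.55 (SD, n = 10). The exact adjusted p was 0.0207, and 10 of 10 restraint arrays lay below their control mean (adjusted p = 0.184 with an estimated correlation). All 14 had a negative log2 change, 5 passed by themselves, and 13 fell adjusted over the list alone, among them Klf1, the main erythroid transcription factor (-2.06 ± 0.49 SE). The 8 measured B lineage markers fell by 0.88 ± 0.21 SE (exact adjusted p = 0.0098, lower on 10 of 10 arrays; adjusted p = 0.128 with an estimated correlation). Rag1, the recombinase of antigen receptor genes (-2.05 ± 0.41 SE), and Vpreb3, a pre-B cell gene detected on 0 restraint and 4 control arrays, passed and 6 did not. Rag1 was detected on 3 and Klf1 on 2 restraint arrays. The other 13 cell type lists did not pass. Adrb1 and Adrb3 were detected on 0 arrays. Nr3c1, the glucocorticoid receptor gene (-0.26, limma adjusted p = 0.607), Trp53 (0.03, 0.960), Il6 (0.51, 0.303), Il1b (0.45, 0.264), Cxcl12 (0.04, 0.976), Vegfa (-0.02, 0.982), Mpo (-0.06, 0.872) and Prkdc (-0.15, 0.602), the gene mutated in SCID mice and detected on 7 arrays, did not pass either. Cdkn2a was detected on at most 1 array and was not tested, and Mki67 has 0 probes on the array.

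**Figure D1:**
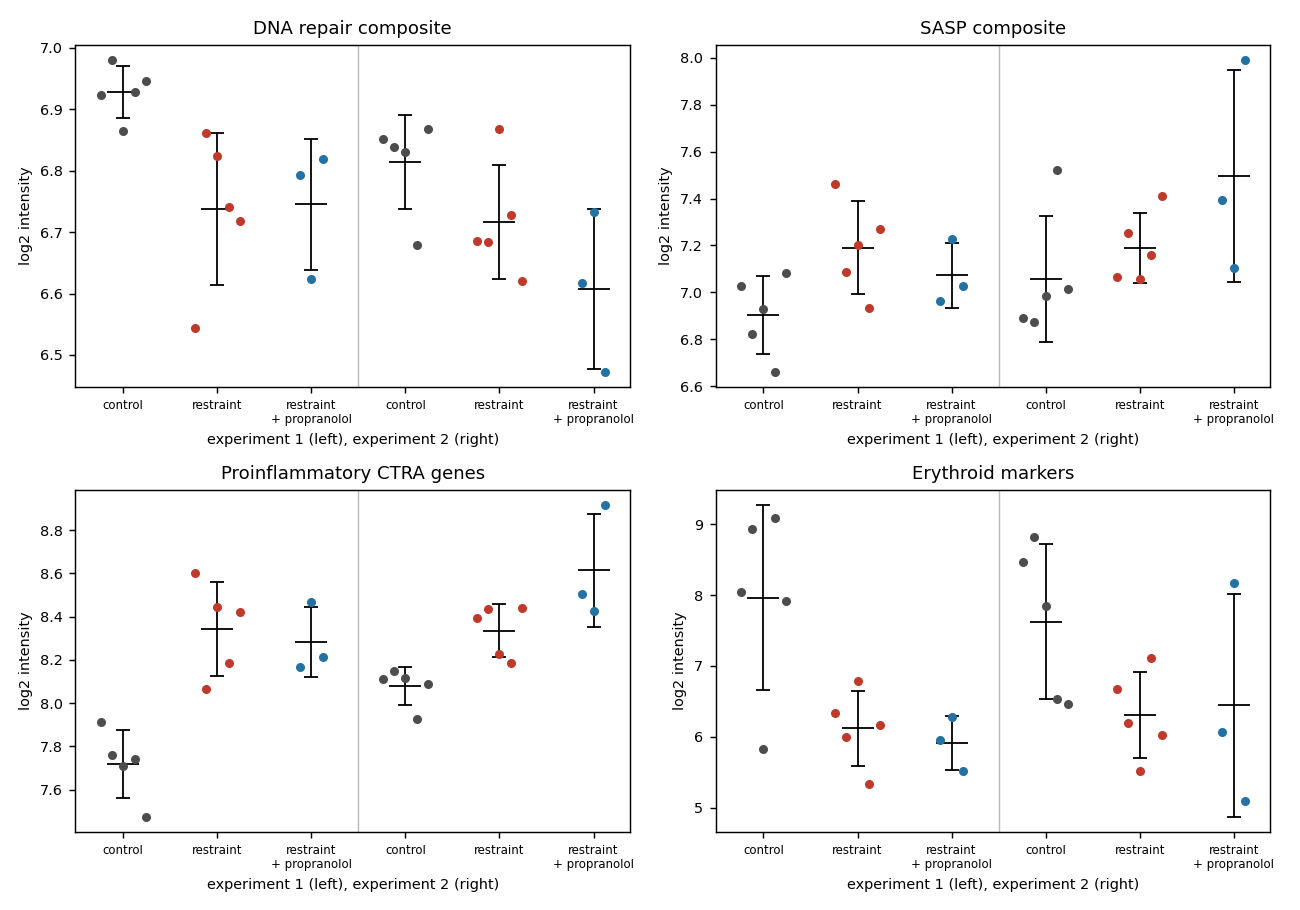
Mean log2 intensity per array (points) of the DNA repair composite, the SASP composite, the proinflammatory CTRA genes and the erythroid markers, by condition, with experiment 1 on the left and experiment 2 on the right of each panel; lines give the group mean and bars its SD (n = 5, 5 and 3 per experiment). The 10 restraint arrays average 6.73 for DNA repair against 6.87 for the 10 control arrays, and 6.22 against 7.79 for erythroid markers.

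By experiment, in order 1 and 2, the CTRA list differed by 0.62 and 0.26, SASP by 0.29 and 0.13, p53 by 0.33 and 0.18, and glucocorticoid by 0.24 and 0.25. Erythroid markers differed by -1.84 and -1.32 and B lineage markers by -0.94 and -0.82. The difference between experiments had an unadjusted limma p of 0.0242 for CTRA and 0.0509 for immediate early genes. That p was 0.0217 for megakaryocyte and platelet markers and 0.0384 for heat shock genes. None of the 105 such tests of lists and composites passed (smallest limma adjusted p = 0.667). Within experiments, limma called 35 genes in experiment 1 (30 up, 5 down) and 2 in experiment 2, Cd83 (1.32) and Ppm1k (-1.26), the latter chosen after its value was seen. The difference between the experiments was called for 0 genes (limma interaction, 355 genes at unadjusted p under 0.05, 1 with array weights, Ear10, chosen after its value was seen), and across genes the log2 changes of both experiments had r = 0.48, where genes are not independent replicates. The arrays lie on 4 beadchip slides on which conditions are unevenly spread. On slides 1 and 3 the control arrays fill the first positions and the restraint arrays come after them. Position and condition cannot be told apart there. With slide as a fixed term 78 genes were called (62 up, 16 down), 68 of them among the 241, and the DNA repair composite differed by -0.13 (limma adjusted p = 0.268) and SASP by 0.17 (limma adjusted p = 0.382). All 241 kept their sign. Under that term the CTRA (0.52), glucocorticoid (0.33), p53 (0.29) and immediate early (0.37) lists passed, and the recombination (-0.30), damage signalling (-0.14), erythroid (-0.99) and B lineage (-0.53) lists did not (limma adjusted p = 0.0629, 0.271, 0.378 and 0.271). With slide as a random block 240 genes were called and the composite differed by -0.14 (limma adjusted p = 0.0189). Within slide 1, which holds 3 restraint and 5 control arrays of experiment 1, the composite differed by -0.19 (exact permutation p = 0.0179, the smallest that slide allows), and SASP by 0.35 (exact p = 0.0357). Recombination differed there by -0.38 (exact p = 0.0179), damage signalling by -0.17 (exact p = 0.0357), CTRA by 0.65 (exact p = 0.0179), glucocorticoid by 0.33 (exact p = 0.0357), p53 by 0.29 (exact p = 0.0357), immediate early by 0.44 (exact p = 0.0179). Erythroid markers differed there by -1.59 (exact p = 0.107) and B lineage by -0.81 (exact p = 0.125). Within slide 3, which holds 5 restraint and 2 control arrays of experiment 2, the composite differed by -0.06 (exact p = 0.762), and SASP by -0.08 (exact p = 0.762). Recombination differed there by -0.21 (exact p = 0.0476, the smallest that slide allows), damage signalling by -0.08 (exact p = 0.381), CTRA by 0.33 (exact p = 0.0476), and glucocorticoid by 0.35 (exact p = 0.0476). There p53 differed by 0.28 (exact p = 0.238), immediate early by 0.27 (exact p = 0.190), erythroid by -0.19 (exact p = 0.667) and B lineage by -0.13 (exact p = 0.190). Of the 2 controls on slide 3, replicate 4 stands apart (DNA repair 6.68 and SASP 7.52, against 6.87 and 7.01 on replicate 5). Without it 1 control array is left, so that only sizes are given. DNA repair then differed by -0.15, SASP by 0.18, p53 by 0.10, immediate early by 0.07, CTRA by 0.25, erythroid by -0.15 and B lineage by -0.27. Within each of these slides limma called 0 genes.

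The count of 241 genes moved by over 1.5 times when any of 10 arrays was left out: to 106 without restraint replicate 1, 158 without restraint replicate 5, and 155, 115, 131 and 148 without control replicates 1, 2, 4 and 5 of experiment 1. In experiment 2 it moved to 131 and 144 without control replicates 1 and 2, and 152 and 158 without restraint replicates 2 and 5. In each of these 10 fits more genes rose than fell, against 112 up and 129 down with all arrays. In most of the other 16 fits with 1 array left out more genes fell than rose. The count was 135 (79 up, 56 down) with no filter on dim probes and 713 (296 up, 417 down) with array weights. It was 402 (171 up, 231 down, 208 shared) without the 3 arrays of lowest array weight, an alternative chosen after seeing the data. With median scaling, where the count was 226, 83 genes rose and 143 fell. Without those 3 arrays the SASP difference was 0.29 and passed (exact permutation, adjusted p = 0.0034). It passed too when control replicate 1 (0.22), control replicate 5 (0.23) or restraint replicate 4 (0.24) of experiment 1, or control replicate 4 (0.27) of experiment 2 was left out. The same holds without restraint plus propranolol replicate 1 of experiment 1 or replicate 2 of experiment 2. Those arrays do not enter this difference (0.21 in both fits), so that only the adjustment over the composite tests moved. Among the genes named above, Il1a kept its call in 6, Eraf in 14, Alas2 in 13 and Blm in 15 of the 26 fits with 1 array left out, and Cd83, Rhov, Icam1, Gadd45b and Pde4b kept theirs in all 26. Over all comparisons, 50 of 94 calls of genes that the rule names held in all 26 fits, and 44 were lost in 1 or more. The immediate early list lost its call without any array other than restraint replicate 2 of experiment 1 and control replicates 1 and 2, restraint replicate 4 and restraint plus propranolol replicate 2 of experiment 2, with adjusted exact permutation p up to 0.0977. Where a restraint plus propranolol array was left out, its difference did not change and only the adjustment over the list tests moved.

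The second comparison, restraint plus propranolol against restraint, addresses which of these transcripts depend on beta-adrenergic signalling. No gene passed: limma called 0 genes, with 661 at an unadjusted p under 0.05 where chance gives 539.6, and the smallest adjusted p was 0.0810. The genes nearest to the threshold were lower with propranolol on 6 of 6 arrays. They were Nlrc3, a regulator of innate immune signalling (log2 change -0.80 ± 0.15 SE), the histone gene H2bc8 (-0.96 ± 0.19 SE), both at limma adjusted p = 0.0810, and Emc9 (-1.08 ± 0.21 SE, limma adjusted p = 0.0895), followed by Fut7 (-0.61) and Il18r1, an interleukin 18 receptor chain (-0.69). The smallest unadjusted p among positive log2 changes belonged to Ufsp1 (0.94), the clock gene Per2 (1.03), Schip1 (1.18), Samsn1 (0.46) and Slc49a4 (0.54). Fos, an immediate early gene, had a log2 change of -0.91 ± 0.20 SE (limma adjusted p = 0.151, lower on 6 of 6 arrays).

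No transcript that restraint changed passed the test for a difference with propranolol. Cdkn1a differed by 0.20 ± 0.19 SE, Tnf by 0.46 ± 0.22 SE and Icam1 by 0.56 ± 0.16 SE, with limma adjusted p of 0.917, 0.795 and 0.491. Nr3c1 (0.38), Trp53 (-0.09), Prkdc (0.07), Il6 (0.12), Il1b (0.18), Cxcl12 (-0.40), Vegfa (0.17) and Mpo (-0.09) did not pass. The DNA repair composite was 6.68 ± 0.13 (SD, n = 6) with propranolol and 6.73 ± 0.10 (SD, n = 10) without, a difference of -0.05 ± 0.05 SE (exact permutation p = 0.400, adjusted p = 0.480, lower on 3 of 6 arrays). The SASP composite was 7.28 ± 0.38 (SD, n = 6) against 7.19 ± 0.16 (SD, n = 10), a difference of 0.09 ± 0.12 SE (exact permutation p = 0.534, adjusted p = 0.534, higher on 3 of 6 arrays). Its sign was not stable: it was -0.12 in experiment 1 and 0.31 in experiment 2, -0.03 without restraint plus propranolol replicate 3 of experiment 2 (SASP 7.99), and -0.02 with array weights. Of the 33 lists 0 passed the exact permutation test. The lists of smallest p were non-homologous end joining (-0.19 ± 0.08 SE, exact adjusted p = 0.160, lower on 5 of 6 arrays) and dendritic cell markers (-0.18 ± 0.08 SE, exact adjusted p = 0.171, lower on 6 of 6 arrays). Proinflammatory CTRA genes differed by 0.11 ± 0.10 SE (exact adjusted p = 0.614), glucocorticoid response genes by 0.01 (exact adjusted p = 0.896) and erythroid markers by -0.03 ± 0.49 SE (exact adjusted p = 0.960).

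With array weights limma called 7 genes here (2 up, 5 down), among them Fos (-1.14), H2bc8 (-0.96), Il18r1 (-0.68) and Per2 (1.06), with Kmo (-0.77), Nme7 (-0.52) and Rabgef1 (1.37) chosen after their values were seen; with only these conditions in the fit it called 1, Per2. Leaving out 1 array gave Nlrc3 (without restraint replicate 2 of experiment 2), Emc9 and Nme7 (without restraint replicate 5 of experiment 2) or H2bc8 (without restraint plus propranolol replicate 2 of experiment 2). The difference between the experiments was called for 0 genes (limma interaction, 554 at unadjusted p under 0.05), for 9 with slide as a fixed term, and for 17 without restraint plus propranolol replicate 2 of experiment 2. With slide as a fixed term the DNA repair composite differed by -0.02 (limma adjusted p = 0.808) and SASP by 0.04 (limma adjusted p = 0.808). Within slide 2, which holds 3 restraint plus propranolol and 2 restraint arrays of experiment 1 and allows no p below 0.1, they differed by 0.02 (exact p = 1) and -0.03 (exact p = 0.8). Within slide 3, with 1 array against 5 of experiment 2 and no p below 0.167, they differed by -0.10 and 0.20 (exact p = 0.333 for both).

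The third comparison, restraint plus propranolol against control, shows how far restrained mice given propranolol stood from unrestrained ones. Their marrow had more proinflammatory and fewer DNA repair and B cell precursor transcripts than control marrow. None of these group calls held when camera estimated the correlation between genes (adjusted p = 0.0676, 0.0843 and 0.184). The B cell precursor call was lost in 13 of 26 fits with 1 array left out. Cd83 rose 3.83-fold (log2 change 1.94 ± 0.20 SE, 6 against 10 arrays, limma adjusted p = 5.8e-06) and Icam1 2.73-fold (1.45 ± 0.16 SE, limma adjusted p = 1.2e-05), both on 6 of 6 arrays. Fos was 3.20-fold lower (-1.68 ± 0.20 SE, limma adjusted p = 2.0e-05, 6 of 6 arrays). Il10, an anti-inflammatory cytokine gene, was detected on 5 of 6 treated and 0 control arrays and was at least 3.69-fold higher. In total limma called 410 genes, 200 up and 210 down, of which 340 changed by at least 1.5-fold.

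The 10 largest rises were of Il10, Il1a, Hcar2, Rhov, Cd83, Schip1, Dusp4, Rora, Nlrp3 and Upp1, and the 10 largest falls of Slc38a5, Abcb4, Rag1, Bcl7a, Fos, Ovca2, Denn2b, Rassf4, Mblac2 and H2ac6. Of the latter Slc38a5 was detected on 1, Abcb4, Rag1 and H2ac6 on 2 and Mblac2 on 4 of 6 treated arrays, so that their sizes and order are not exact. These ranks rest on 1 probe per gene, and other probes differed: Rora had 1.73 on the chosen probe and -0.10 on its other, Schip1 1.93 and 0.41, Dusp4 1.75 and at the lowest 0.39, and Rassf4 -1.56 and at the highest 0.01. The DNA repair composite was 6.68 ± 0.13 (SD, n = 6) against 6.87 ± 0.08 (SD, n = 10), a difference of -0.19 ± 0.05 SE (exact permutation p = 0.00096, adjusted p = 0.00574, lower on 6 of 6 arrays; adjusted p = 0.0843 with an estimated correlation). Of its 126 genes 7 fell, 1 rose and 118 did not pass. The genes that fell were Rad52 (-1.03), Gen1 and Rad54b (-1.07) of homologous recombination, Msh6 (-0.45) of mismatch repair, Gtf2h3 (-0.47) of nucleotide excision repair, Xrcc6 (-0.74), which encodes a DNA end-binding protein, and Aplf (-1.19), and the gene that rose was Per1 (0.90). Homologous recombination and Fanconi anemia fell by 0.34 (exact adjusted p = 0.0098), damage signalling by 0.15 (exact adjusted p = 0.0098) and mismatch repair by 0.21 (exact adjusted p = 0.0291), each lower on 6 of 6 arrays. None of these calls held when camera estimated the correlation between genes (adjusted p = 0.307, 0.333 and 0.419). Base excision repair (-0.19, exact adjusted p = 0.0975), non-homologous end joining (-0.19, 0.0947) and nucleotide excision repair (-0.09, 0.355) did not pass.

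Proinflammatory CTRA genes rose by 0.55 ± 0.10 SE (exact adjusted p = 0.00935, higher on 6 of 6 arrays; adjusted p = 0.0676 with an estimated correlation), with 7 members up, 2 down and 7 not passing. Tnf (1.54), Rel (1.36) and Nfkb2 (1.11) rose. The SASP composite was 7.28 ± 0.38 (SD, n = 6) against 6.98 ± 0.22 (SD, n = 10); its difference of 0.30 ± 0.12 SE did not pass (exact permutation p = 0.0379, adjusted p = 0.0569, higher on 6 of 6 arrays). Its proteases, receptors and matrix part rose by 0.41 ± 0.12 SE (exact adjusted p = 0.0237; adjusted p = 0.121 with an estimated correlation), with Icam1 and Plaur (0.55), the urokinase receptor gene, past the test and 15 genes not passing. Its soluble factors did not pass (0.24, exact adjusted p = 0.380), although Cxcl2, a neutrophil chemokine gene (0.79), and Il1a rose. Glucocorticoid response genes rose by 0.26 (exact adjusted p = 0.0158; adjusted p = 0.131 with an estimated correlation), with 5 members up and 2 down, Tsc22d3 (-0.59) and Dusp1 (-0.60), both known glucocorticoid targets, and 10 not passing. The other probe of Tsc22d3 differed by -0.18. Cell cycle inhibitors and p53 targets rose by 0.23 (exact adjusted p = 0.0493; adjusted p = 0.184 with an estimated correlation), with Gadd45b (1.39), Bbc3 (0.50), Cdkn1a (0.89) and Mdm2 (0.31) past the test. This call is at the threshold and held in 6 of the 26 fits with 1 array left out. Some of the losses came from restraint arrays, which do not enter this difference and move only the adjustment. Immediate early genes did not pass as a list (0.26, exact adjusted p = 0.0764), with 7 members up, 3 down and 15 not passing, Nr4a2 (1.33), Pde4b (1.39) and Pde4d (1.08) among the former. B lineage markers fell by 1.03 ± 0.24 SE (exact adjusted p = 0.0474, lower on 6 of 6 arrays; adjusted p = 0.184 with an estimated correlation), with Rag1 and Dntt (-1.51) past the test. Erythroid markers differed by -1.61 ± 0.49 SE, lower on 5 of 6 arrays, and did not pass (exact adjusted p = 0.0947). Proliferation (-0.25, exact adjusted p = 0.194) and MHC class II genes (0.24, exact adjusted p = 0.404) did not pass.

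Limma called 65 genes within experiment 1 and 99 within experiment 2, and 0 for the difference between them (572 at unadjusted p under 0.05); that count was 1, Nr4a1, chosen after its value was seen, without control replicate 4 and 6 without restraint plus propranolol replicate 2 of experiment 2. The 410 became 240 with replicate number as a block, 928 with array weights, 234 without restraint plus propranolol replicate 2 of experiment 1, 259 without replicate 3 of that condition in experiment 2, and 313 without the 3 arrays of lowest weight (171 up, 142 down, 229 shared). With slide as a fixed term 23 genes were called (22 shared), and all 410 kept their sign. Slide 4 holds only restraint plus propranolol replicates 2 and 3 of experiment 2, which that term takes out of the contrast. The lower count can thus come from lost arrays as well as from slide. With that term the DNA repair composite differed by -0.16 (limma adjusted p = 0.357) and SASP by 0.21 (limma adjusted p = 0.440). Of the lists CTRA (0.55, limma adjusted p = 0.0245) and glucocorticoid (0.40, limma adjusted p = 0.0179) passed, and homologous recombination (-0.34), damage signalling (-0.17), mismatch repair (-0.17), SASP proteases (0.33), p53 (0.29) and B lineage genes (-0.57) did not. With slide as a random block 407 genes were called, the composite differed by -0.19 (limma adjusted p = 0.0102) and SASP by 0.30 (limma adjusted p = 0.0386). The only slide with both conditions of 1 experiment, slide 3, holds 1 array against 2, and there the composite differed by -0.16 (exact p = 0.667, none below 0.333 possible), SASP by 0.12, CTRA by 0.50 and B lineage by -0.39. Without control replicate 4, which stands apart, 1 array is left on each side, and these were -0.25, 0.38, 0.41 and -0.53. Without the 3 arrays of lowest weight SASP passed (0.26, exact permutation, adjusted p = 0.00857). It also passed without control replicate 1 (0.32), control replicate 5 (0.32) or restraint plus propranolol replicate 1 (0.33) of experiment 1, and without control replicate 4 (0.36) or restraint plus propranolol replicate 2 (0.40) of experiment 2. Leaving out 1 array ended the p53 call for 20 of 26 arrays (adjusted exact permutation p up to 0.145), all but restraint replicates 2 and 4 of experiment 1 and control replicates 3 and 4 and restraint replicates 3 and 4 of experiment 2. For the restraint arrays among the 20, the p53 difference did not change and only the adjustment over the list tests moved. Leaving out 1 array ended the B lineage call for 13 arrays (adjusted exact permutation p up to 0.0886). These were control replicates 1, 2, 4 and 5 and all 3 restraint plus propranolol arrays of experiment 1, and in experiment 2 control replicates 1, 2, 3 and 5 and restraint plus propranolol replicates 1 and 3. It ended the mismatch repair call for control replicates 1, 2, 4 and 5 of experiment 1 and control replicates 1 and 5 and restraint plus propranolol replicate 2 of experiment 2 (up to 0.0689). It ended the SASP protease call for restraint plus propranolol replicate 2 of experiment 1 and control replicates 1 and 5 and restraint plus propranolol replicates 1 and 3 of experiment 2 (up to 0.0702).

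**Figure D2:**
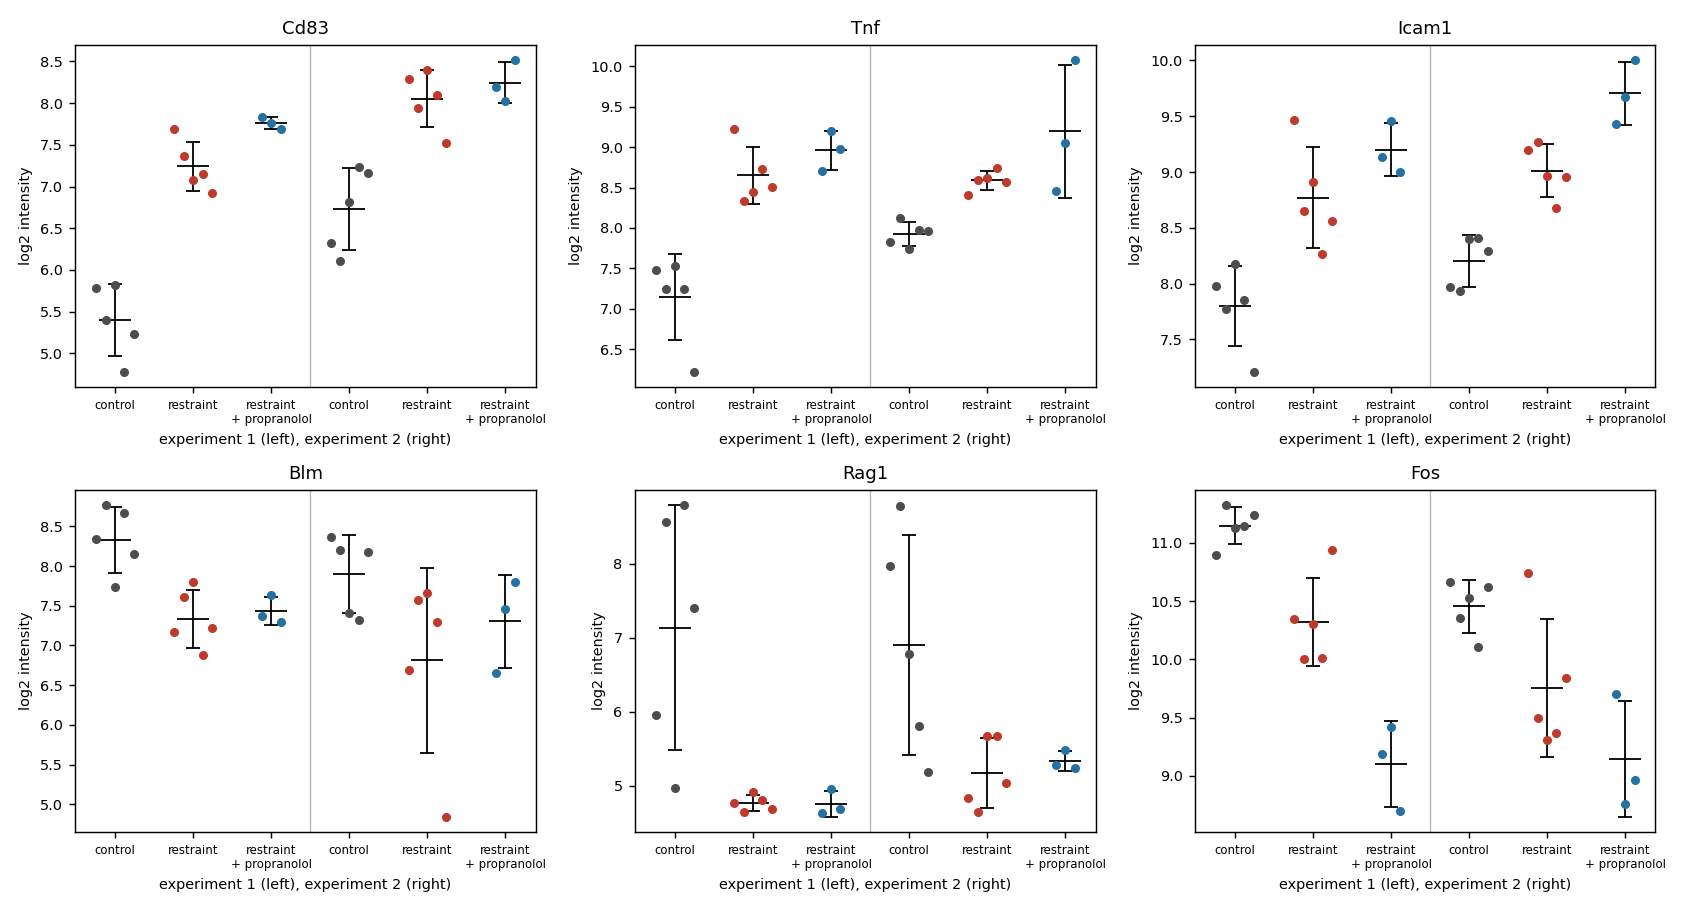
Log2 intensity per array (points) of Cd83, Tnf, Icam1, Blm, Rag1 and Fos by condition, with experiment 1 on the left and experiment 2 on the right of each panel; lines give the group mean and bars its SD (n = 5, 5 and 3 per experiment). Cd83 averages 6.07 on control, 7.65 on restraint and 8.00 on restraint plus propranolol arrays, and Fos 10.80, 10.04 and 9.12.

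**Figure D3:**
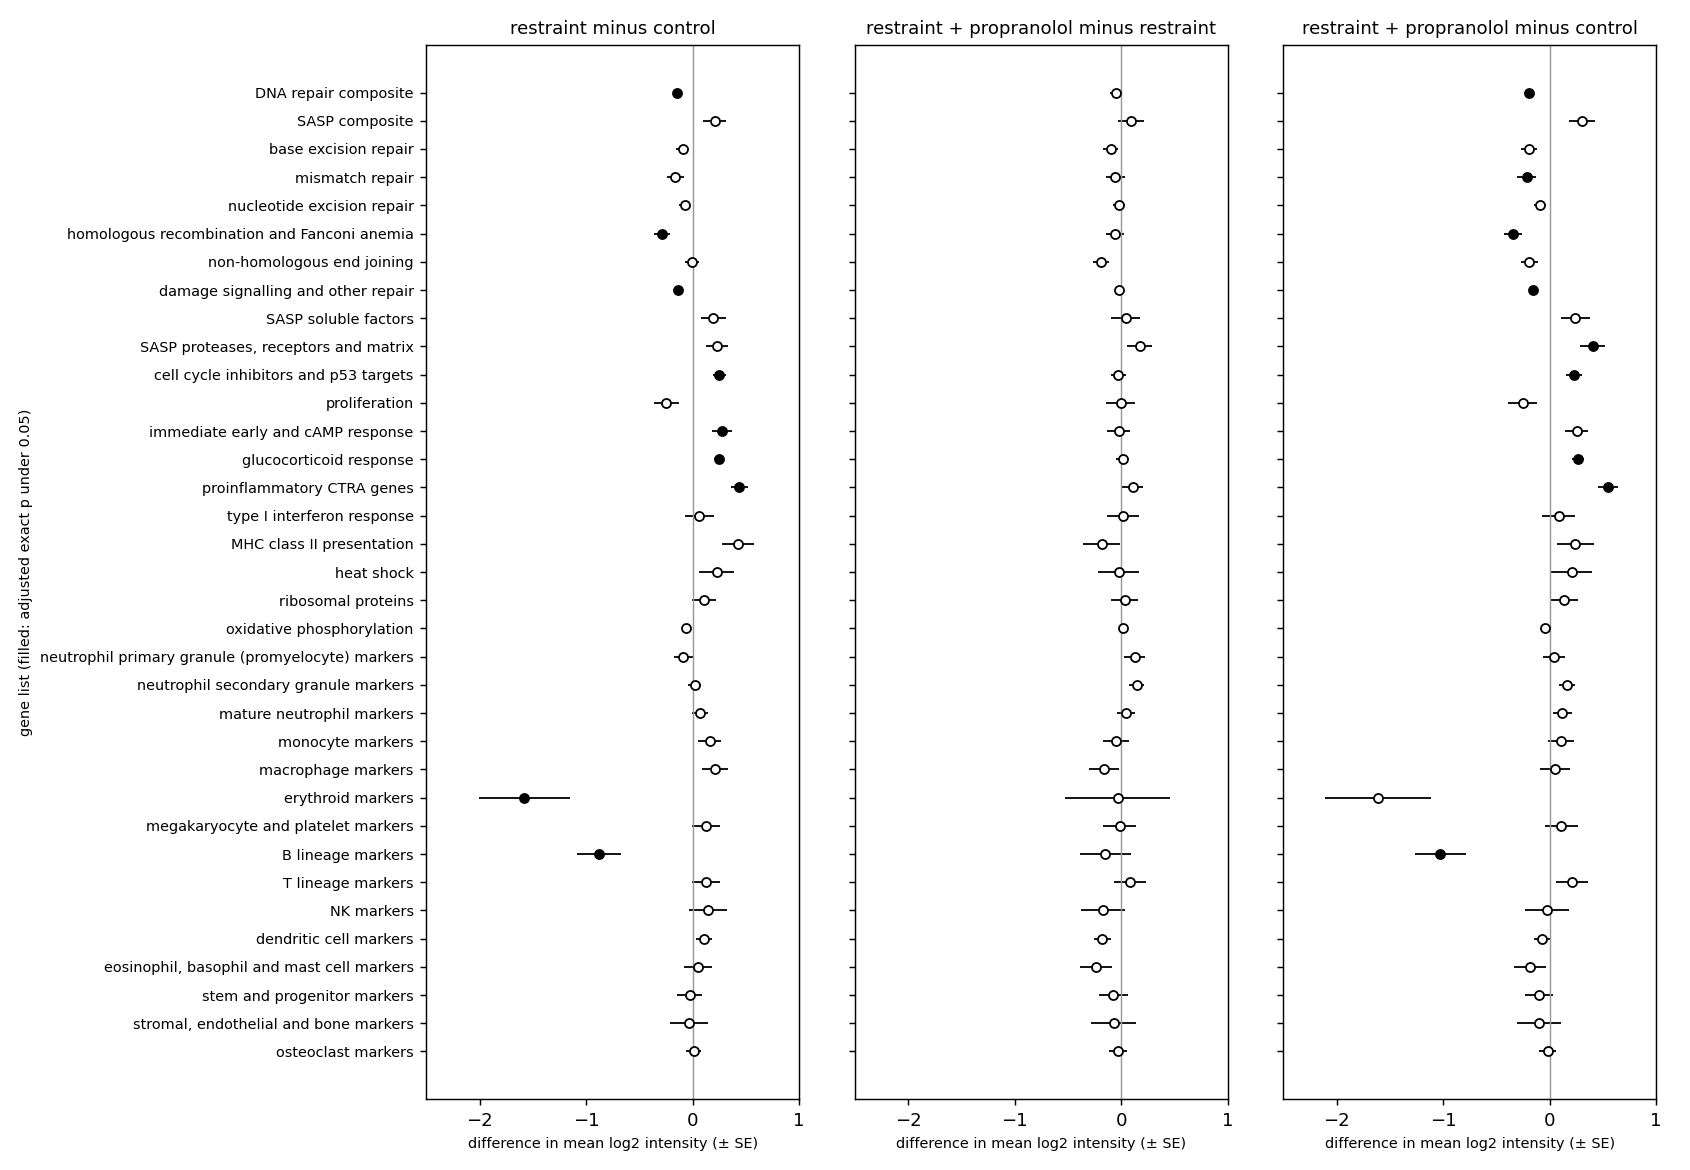
Difference in mean log2 intensity (points, with SE bars) of the 2 composites and 33 gene lists in the 3 comparisons; filled points have an adjusted exact permutation p under 0.05. In restraint against control 8 lists and the DNA repair composite are filled, in restraint plus propranolol against restraint none.

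The direction of the propranolol difference was set against that of restraint. Across the 10792 genes, which are not independent replicates, the restraint and the propranolol-against-restraint log2 changes had r = -0.06 and a covariance of -0.00478. These contrasts share the restraint arrays, and in 100 simulations of unchanged groups that sharing alone gave r = -0.46 (-0.75 to 0.06) and a covariance of -0.0236. When the restraint arrays were split so that each contrast used different ones, r averaged 0.16 over 100 splits (0.02 to 0.34). That average was 0.0883 without restraint replicate 4, 0.249 without restraint plus propranolol replicate 2 and 0.0770 without its replicate 3, all of experiment 2. It was 0.254 with slide as a fixed term, 0.0344 with array weights and 0.0245 without the 3 arrays of lowest weight. The restraint and the restraint-plus-propranolol changes against control had r = 0.76 and a covariance of 0.0889, where the shared control arrays alone gave r = 0.37 (-0.22 to 0.69) and a covariance of 0.0182 in simulations. With the control arrays split r was 0.53 (0.29 to 0.68). Of the genes called in both contrasts with control, 82 rose in both, where independent calls would share 2.08, and 52 fell in both, against 2.51, and the shared controls raise these overlaps too.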

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

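The tests against the mature neutrophil markers, of the erythroid difference within slides, without the 3 arrays of low weight and within slides, and the counts of other splits for propranolol against restraint and for the differences between experiments were chosen only after the result was seen. In the groups of 5 arrays, 348 pairs of a group and a value were tested for an array far from the rest of its group, and groups of 3 were not. An array stood apart in 37, where chance gives about 1 in 20, or 17.4. Experiment 2 control replicate 4 accounts for 13 and experiment 1 control replicate 5 for 6.

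The lower DNA repair composite after restraint (-0.14) could come from fewer erythroid or B lineage cells in the sorted population or from the slides. After removing the within-group slope on erythroid markers the difference was -0.10 (exact permutation p = 0.0191), which argues against erythroid cells as the whole cause. After removing the slope on B lineage markers it was -0.0796 (exact permutation p = 0.0426), which argues against B lineage cells alone as the whole cause. The mean of the differences within slides 1 and 3 was -0.12 (exact permutation p = 0.0408), which argues against slide as the whole cause. The difference was smaller on slide 3 than on slide 1. On both slides the control arrays sit before the restraint arrays, and an effect of position was not tested. The corrections made the difference smaller, so that a part carried by cell types stays open, and the call ends with slide as a fixed term (-0.13, limma adjusted p = 0.268). The erythroid and B lineage slopes were removed 1 at a time, so that a joint loss of both lineages was not tested and stays open. The slopes rest on weak within-group correlations (r = 0.30 and 0.37) and can correct too little. Proliferation genes were also lower on average after restraint, without passing as a list. No correction on them was run, so that a part that goes with proliferation stays open. Restraint itself, the difference the design names, stays among the open explanations and was not tested apart from the others.

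The higher proinflammatory CTRA genes after restraint (0.44) could come from arrays that stand apart, from the slides, or from other cells taking the share that erythroid cells left. Without the 3 arrays of lowest weight the difference was 0.39 (exact permutation p = 0.00025), and the mean within slides 1 and 3 was 0.49 (exact permutation p = 0.00085). Minus the difference of the mature neutrophil markers it was 0.37 (exact permutation p = 0.00054), so that these genes rose by more than those markers. A gain shared evenly by all remaining cells would raise both alike. A gain of particular cells, such as monocytes or macrophages, was not tested and stays open. Array position goes with condition within slides 1 and 3 and was not tested. The values argue against the arrays, the slides and an evenly shared gain as the whole cause. A response of marrow leukocytes to restraint is consistent with them as a hypothesis, found and tested on the same data.

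The lower erythroid markers after restraint (-1.58) go with arrays out of place in experiment 1. There control replicate 3 had an erythroid mean of 5.83 (other controls of experiment 1 7.92 to 9.09) and restraint replicate 3 one of 6.78 (other restraint arrays of experiment 1 5.33 to 6.34). A swap of these could account for that, but the CTRA mean of restraint replicate 3 exceeded that of control replicate 3 by 0.73 (8.44 against 7.71), as between the groups, which argues against a swap. In experiment 2 the groups overlapped too. Control replicates 4 and 5 had 6.53 and 6.46 (other controls 7.84 or more), and restraint replicates 1 and 4 had 6.68 and 7.11 (other restraint arrays 6.20 or less). Without the 3 arrays of lowest weight the difference was -1.72 (exact permutation p = 0.0022), which argues against those arrays. Within slides 1 and 3 the mean difference was -0.89 (exact permutation p = 0.0876), so that slide and condition cannot be told apart for these markers. Slide 3 holds 2 control arrays, with erythroid means of 6.53 (replicate 4, which stands apart) and 6.46 (replicate 5). Without replicate 4 the difference on that slide was -0.15, so that its small size does not rest on that array. The hemoglobin genes averaged 9.28 (Hbb-b1) and 10.62 (Hba-a1) on control and 7.60 and 8.60 on restraint arrays, where probes of near-identical copies may share signal, and how far the leukocyte gate removes erythroid cells is not given.

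For restraint against control, chance alone is an unlikely source of the gene count. Of 100 splits of the arrays within experiments, 1, the real one, gave as many as 241 genes, and the highest other gave 0. The same holds for restraint plus propranolol against control, where 1 of 100 splits gave as many as 410 and the highest other gave 31. The splits exchanged arrays between slides, so they do not test slide. With slide as a fixed term the counts for these comparisons with control were 78 and 23. For restraint plus propranolol against restraint and for the differences between experiments the real count is 0, which all 100 splits reach whatever the data, so that these splits say nothing about chance. Their highest other counts were 2 for restraint plus propranolol against restraint, and for the differences between experiments 5 for restraint, 9 for propranolol against restraint and 41 for restraint plus propranolol against control.

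Experiment 2 control replicate 4 had 42.5% of probes detected (other arrays of its group 47.9% or more) and a median Spearman correlation with the other arrays of 0.845 (others 0.923 to 0.931). Its means were 6.68 for the DNA repair composite (others 6.83 to 6.87), 7.52 for the SASP composite (6.88 to 7.01), 7.49 for nucleotide excision repair (7.82 to 7.87) and 7.59 for SASP soluble factors (6.76 to 6.95). They were 8.37 for immediate early genes (8.75 to 8.89), 7.93 for CTRA genes (8.09 to 8.15), 7.88 for interferon genes (7.46 to 7.58), 5.53 for T lineage markers (5.92 to 6.05) and 7.35 for stem and progenitor markers (6.53 to 6.76). Its log2 intensity was 4.62 for Pim1 (others 6.18 or more) and 8.87 for Il1b (9.79 to 10.13).

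Experiment 1 control replicate 5 had a median correlation of 0.880 (others 0.925 to 0.932), 9.48 for ribosomal proteins (10.12 to 10.36), 4.58 for Nlrp3 (6.82 to 7.62), 6.22 for Tnf (7.25 to 7.54), 8.46 for Per2 (6.79 to 7.26) and 7.54 for Mblac2 (6.60 to 6.77). Experiment 1 restraint replicate 1 had 5.90 for homologous recombination (6.26 to 6.40) and 8.89 for neutrophil primary granule markers (9.31 to 9.47).

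Experiment 1 control replicate 3 was low in Eraf (4.94, others 9.89 to 11.02), Rhd (4.33, 8.95 to 9.81), Alas2 (5.27, 8.83 to 10.20) and Slc6a9 (4.78, 8.12 to 9.24). Experiment 1 restraint replicate 3 was high in Eraf (7.44, others 4.47 to 4.98), Slc38a5 (7.47, 4.34 to 4.53), Btnl10 (4.60, 4.29 to 4.36) and Trim10 (4.87, 4.32 to 4.45). Experiment 2 restraint replicate 4 was high in Rhd (8.07, others 4.42 to 5.07) and Trim10 (5.79, 4.27 to 4.62).

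The remaining values come from 1 array each. In experiment 1, control replicate 2 had 8.30 for interferon genes (others 7.47 to 7.68), control replicate 4 had 6.93 for T lineage markers (5.76 to 6.09) and restraint replicate 4 had 7.97 for Trp53 (7.14 to 7.28). In experiment 2, restraint replicate 3 had 10.17 for mature neutrophil markers (others 10.51 to 10.60), replicate 2 had 7.01 for Fut7 (7.47 to 7.56) and replicate 5 had 7.20 for the histone gene H2ac6 (4.58 to 4.78).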

How the results depend on the processing

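The fit without 3 arrays and the comparisons within slides were chosen only after the result was seen. No composite changed direction under a setting that ended or made its call, and the cause of the changes below was not tested. The number of genes changed by restraint (241) was 135 with no filter on dim probes, 78 with slide as a fixed term, in both of which more genes rose than fell (79 and 56, 62 and 16, against 112 and 129), 713 with array weights (296 up, 417 down), 35 within experiment 1, 2 within experiment 2, 402 without the 3 arrays (171 up, 231 down), 0 within slide 1 and 0 within slide 3, which hold fewer arrays, and 106 to 339 with 1 array left out. The difference between experiments for restraint (0 genes) was 1 with array weights and 0 to 0 with 1 array left out. For propranolol against restraint (0 genes) it was 7 with array weights, 1 with only the conditions compared and 0 to 2 with 1 array left out, and its difference between experiments (0) was 9 with slide as a fixed term and 0 to 17. For restraint plus propranolol against control (410) it was 23 with slide as a fixed term, 240 with the replicate block, 928 with array weights, 65 and 99 within experiments 1 and 2, and 234 to 503 with 1 array left out (200 up and 210 down became 171 and 142 without the 3 arrays), and its difference between experiments (0) was 0 to 6. The DNA repair composite missed the threshold with slide as a fixed term (-0.13 for restraint, -0.16 for restraint plus propranolol against control), with camera's estimated correlation (p = 0.0843 for both) and within slide 3 (-0.0562, and -0.150 there with 1 control array, where fewer arrays allow no p below 0.167), and with 1 array left out it was -0.16 to -0.12 and -0.23 to -0.16, and -0.08 to -0.02 for propranolol against restraint. The SASP composite, which misses it, passed for restraint and for restraint plus propranolol against control with the deposited normalized matrix (0.12 and 0.20), no background correction (0.12 and 0.20), normexp (0.15 and 0.24), the strict filter (0.27 and 0.36), array weights (0.24 and 0.22), z-scores (0.31 and 0.47), camera's preset correlation (p = 0.00095 and 0.00020, and 0.0252 for propranolol against restraint) and without the 3 arrays (0.29 and 0.26). It also passed for the latter with slide as a random block (0.30) and the replicate block (0.33). Within slide 1 it was 0.35 for restraint at an unadjusted exact p = 0.0357, against an unadjusted exact p = 0.0331 over all arrays, and within slide 3 its sign turned (-0.0793, exact p = 0.762). For propranolol against restraint its sign turned with array weights (-0.0199), without the 3 arrays (-0.0296) and within slide 2 (-0.0289). With 1 array left out it was 0.17 to 0.27 for restraint, -0.03 to 0.19 for propranolol against restraint and 0.18 to 0.40 for restraint plus propranolol against control. The 16 lists became 6 with slide as a fixed term and 0 with camera's estimated correlation. The direction value, the split r of 0.16, was 0.25 with slide as a fixed term, 0.0344 with array weights, 0.0245 without the 3 arrays and 0.0770 to 0.249 with 1 array left out. Over all settings, values of named genes past the threshold stayed past it 3139 times and missed it 610 times, those not past it stayed so 1588 times and passed 8 times, and list calls held 551 times and were lost 129 times. Signal over background limits transcripts near the floor, as 39.5% to 51.2% of probes were detected per array.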

Other observations

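The test of a return under propranolol was chosen only after the result was seen.

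All 10 MHC class II genes had positive log2 changes after restraint, with a list difference of 0.42 ± 0.15 SE (exact adjusted p = 0.0947), and 4 rose adjusted over the list alone. Cd74, the invariant chain gene (0.78, limma adjusted p = 0.0705), and H2-Eb1 (0.87, limma adjusted p = 0.0979) did not pass over all genes. Of the 27 proliferation genes 26 had negative changes. For type I interferon genes the difference was 0.07 (exact adjusted p = 0.834). Heat shock genes (0.23, exact adjusted p = 0.433), ribosomal proteins (0.10, 0.670) and oxidative phosphorylation genes (-0.06, 0.323) did not pass.

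Among cell type markers after restraint, those of neutrophil primary granules (-0.09, exact adjusted p = 0.635), secondary granules (0.02, 0.890), macrophages (0.21, 0.322), megakaryocytes and platelets (0.12, 0.635), T cells (0.12, 0.633), NK cells (0.14, 0.617) and dendritic cells (0.11, 0.411) did not pass. Neither did those of eosinophils, basophils and mast cells (0.05, exact adjusted p = 0.834), stem and progenitor cells (-0.03, 0.914), stromal, endothelial and bone cells (-0.03, 0.936) and osteoclasts (0.01, 0.936). Single members did: Hmox1, the heme oxygenase gene of macrophages (1.01), and Cd28, a T cell costimulatory receptor gene (0.98), rose. In restraint plus propranolol against control, Cd28 (0.98), the decoy interleukin 1 receptor gene Il1r2 (0.64) and the co-chaperone gene Bag3 (0.93) rose, and neutrophil secondary granule markers differed by 0.16 (exact adjusted p = 0.139).

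A further hypothesis was that propranolol returned restraint's changes toward control. Signed by their restraint change, the 241 restraint-changed genes moved by a mean log2 value of 0.00907 ± 0.116 SE with propranolol (exact permutation p = 0.922), with 0.06 in experiment 1 and -0.05 in experiment 2, and 124 of them moved on in the restraint direction. Their mean restraint change was 0.92, and a return halfway to control would give -0.46, farther from the value than its SE. Each of 100 splits then chose its own genes (median 49) with some restraint arrays and measured them against the others. Their mean was 0.23 (0.01 to 0.40), where their mean restraint change was 1.06. These values argue against such a return for restraint-called genes as a set, and a return of single genes stays open. The array of lowest weight (0.146), restraint plus propranolol replicate 3 of experiment 2, entered this test, which was not run without it. Across all genes the split r was 0.0770 without that array and 0.16 with it.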
